A study of Homo sapiens with 4 samples.

How the data were processed

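Gene expression was measured in HCT116 cells, an established human colorectal carcinoma line, on 4 Affymetrix arrays of total RNA. Per the labels' protocols, cells were given 5-aza-2'-deoxycytidine (decitabine, a cytosine analog that is built into DNA and inhibits DNA methyltransferases) at 1 µM, starting 24 hours after seeding, and were dosed again 48 hours after the first dose. RNA from vehicle and treated cells was taken 72 hours after the first dose. Sense-strand cDNA was made with a whole-transcript kit, fragmented, labelled with biotin and hybridized, 1 sample per array. The titles give 2 vehicle and 2 treated samples, numbered 1 and 2 in each group, and do not say whether they came from separate cultures. P-values therefore measure the spread between these samples, which may be technical.

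The deposited table holds log2 values, 1 per probe set and array, made by the authors with Affymetrix Expression Console and the RMA method, per the submitters' processing notes. RMA corrects background, quantile normalizes the arrays and summarizes the probes of each probe set on the log2 scale. Software versions, the probe set definition and the genome build are not given in the sources used here, and the table was not set against scanner files. Its scale was read from the values: 33297 probe sets, none negative, with array medians of 5.73, 5.72, 5.84 and 5.84 for vehicle 1, vehicle 2, treated 1 and treated 2. The values were not centred by probe set. Because quantile normalization forces similar distributions on the arrays, a change of total RNA per cell cannot be seen. The table has no detection calls, so it was not determined which low levels lie above background. RMA folds of genes near background are usually compressed, and a fold from such a level is the fold on this scale. The precision is limited by the number of arrays, 2 per group. Exactly equal values on both arrays of a group occurred for 71 probe sets in vehicle and 112 in treated cells, so the arrays are not copies of each other.

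Probe sets were named through a platform annotation table, in which 0 symbols differed from those of the RefSeq gene table. It gave 1 gene symbol for 19181 probe sets and several for 2055, and it did not list 12061, which are unnamed here and may include control probe sets. Of the probe sets with 1 symbol, 19143 matched the RefSeq table of assembly GRCh38.p14 by gene ID. That table was used for chromosome names and for which genes neighbour each other, and no coordinates are given because the build behind the array annotation is not stated. Each of the 17958 genes was represented by its probe set with the highest mean over all 4 arrays, a choice that mattered for 895 genes. No filter on dim genes was applied. Probe sequences were not used, so hybridization between near-identical members of multigene families (MAGE, SSX, PRAME-like, butyrophilin, KLRC and histone genes) was not assessed, and values of their members are uncertain.

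Treated and vehicle arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with two-sided p-values adjusted by the Benjamini-Hochberg method over all genes. An adjusted p under 0.05 is called a rise or a fall. With 2 arrays against 2, an exact permutation test of a single gene cannot go below 0.333, so each call rests on limma's pooled variance. Log2 fold changes are given with their moderated standard errors (SE), and group levels as mean ± SD of 2 arrays. Before the data were examined, 17 gene lists were fixed and tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 17 lists. The same test with an estimated correlation refers to the 2 residual degrees of freedom, and under it no list passed. Its adjusted p is given beside each call. For the lists that passed at the preset value, the estimated correlations ran from 0.009 (hypermethylated list) to 0.236 (WNT targets). The calls thus rest on the preset value, and the parts of the 2 differences were not separated. The lists overlap in part: 12 autosomal cancer/testis antigens are also in the germline list. Shares of rises were compared with two-sided Fisher exact tests, 4 in that family, in which genes are not independent replicates.

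Also before the data were examined, the genes to name were set by rule: DNMT1, DNMT3A and DNMT3B, the 10 highest and the 10 lowest log2 fold changes among called genes whose arrays did not overlap between groups, and up to 4 members of each list by smallest p-value. This gave 85 genes. Where a list had 5 or fewer calls in 1 direction, its called members outside the rule are named too; these and any other genes outside the rule were chosen after their values were seen.

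The fit was tested on simulated arrays with the real vehicle means and a spread drawn from limma's fitted prior, in 10 runs over the 17958 genes with 200 changed genes each. It recovered 2.6% of genes changed by 0.5 on the log2 scale, 76% of those changed by 1, 99.8% of those changed by 2 and 100% of those changed by 4. Of all calls 4.46% were false, with the spread taken from the fit's own model. These rates hold for 200 changed genes. In the data 5023 genes were called, which makes the Benjamini-Hochberg cutoff less strict, so the recovery rates do not carry over. Changes smaller than 0.5 were called there, such as that of GPI (log2 fold change -0.46). In the same runs camera called 1 of 170 lists without change and all 10 planted lists. Genes were drawn independently there, so false calls among lists of correlated genes were not tested. The planted lists consisted mostly of raised genes, so their calls say little about weaker lists.

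The alternatives were the replicate number as a block, a filter that left out the dimmest 33.3% of genes, another variance prior, other thresholds (adjusted p of 0.01 and 0.1, and a 2-fold minimum), a repeated quantile normalization, centring each array on the housekeeping list, the mean of a gene's probe sets, all named probe sets, a plain test without moderation, each array left out in turn, and, for the lists, an estimated correlation and limma's fry. Random lists matched on vehicle level (10000 per list) and the neighbour shuffles were drawn with fixed seeds. Tables were made with pandas 2.3.3 and plots with matplotlib 3.10.9.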

Results

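Transcript levels were compared between HCT116 cells exposed to the DNA methyltransferase inhibitor 5-aza-2'-deoxycytidine at 1 µM for 72 hours (2 arrays) and vehicle-treated cells (2 arrays). The series title abbreviates its subject as CTA, read here as cancer/testis antigens, which are normally expressed in germ cells and found in some tumors. Values are log2 RMA levels. Over the 33297 probe sets, Pearson's correlation was 0.995 between the vehicle arrays and 0.992 between the treated arrays, and lay between 0.966 and 0.971 for pairs of a vehicle and a treated array. These correlations are across probe sets, which are not independent replicates. Of 17958 genes tested, the median standard error of the log2 fold change was 0.13.

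Treatment was accompanied by very large rises of a limited number of genes and by falls, the largest of which were smaller than the largest rises. The highest rises were of MAGEA4, a cancer/testis antigen, which went from 3.43 ± 0.25 in vehicle to 11.04 ± 0.08 in treated cells (SD, n = 2), 196-fold, and of TKTL1, a transketolase-like protein, which went from 4.86 ± 0.20 to 12.44 ± 0.01, 191-fold. They were followed by DAZL, a germ cell RNA-binding protein (111-fold), UCHL1, a ubiquitin hydrolase of neurons and germ cells (88.9-fold), GCNA, a germ cell nuclear protein (78.8-fold), NNAT, the imprinted neuronatin (77.4-fold), SLC34A2, a sodium-phosphate cotransporter (77.4-fold), ZFP42, a pluripotency-associated zinc finger protein (73.8-fold), the small nucleolar RNA SNORD113-4 (69.5-fold) and CCNA1, the germline cyclin A1 (60.7-fold). SE on the log2 scale lay between 0.12 and 0.23 for these 10 genes, with adjusted p of 1.05e-05 or less. The largest fall was of ANKRD22, an ankyrin repeat protein, which was 18.7-fold lower (log2 fold change -4.22, SE 0.19, adjusted p = 2.27e-05). ADGRF1, an adhesion G protein-coupled receptor, fell from 10.70 ± 0.06 to 7.46 ± 0.12 (9.41-fold lower), and ANXA10, an annexin, was 9.36-fold lower. TNFSF18, a TNF-family ligand, was 7.04-fold lower, and SULT1C2, a sulfotransferase, 6.74-fold lower. RAB26, a small GTPase, was 5.98-fold lower, and LMF1, a lipase maturation factor, 5.83-fold lower. The butyrophilin BTN3A2 was 5.13-fold, MNS1, a meiosis-associated structural protein, 4.98-fold and KLRC4, a lectin-like receptor, 4.45-fold lower, the highest adjusted p among the 10 falls being 0.000528.

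**Figure D1:**
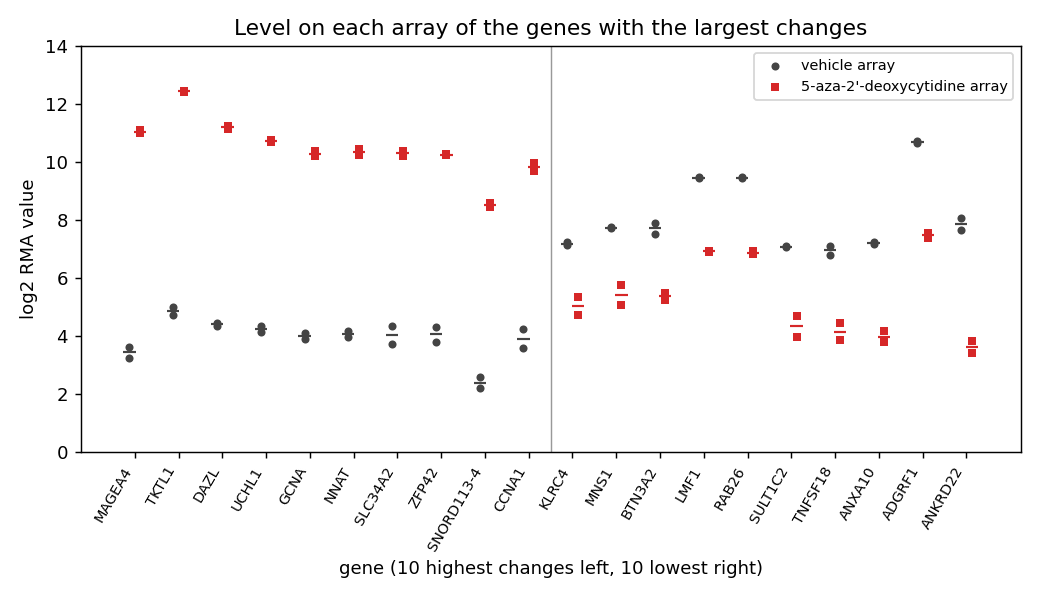
Level of the 10 genes with the highest and the 10 with the lowest log2 fold change, as log2 RMA values on each of the 2 vehicle arrays (circles) and 2 treated arrays (squares), with short horizontal bars at the mean of 2 arrays. The arrays of the 2 groups do not overlap for any of the 20 genes, which were chosen for this; MAGEA4 went from 3.43 to 11.04 and ANKRD22 from 7.85 to 3.63.

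In limma's test 2229 genes rose and 2794 fell. At a 2-fold minimum 907 rose and 470 fell, and at an 8-fold minimum 138 rose and 3 fell. For 65.8% of genes the arrays of the 2 groups did not overlap, against 33.3% by chance. The median gene changed by -0.07 on the log2 scale. Centring the arrays on the housekeeping list moved it by 0.11 and turned the balance to 2694 rises and 1843 falls, 59.4% rises against 44.4% as deposited, so which direction had more calls depended on the scaling. It also depended on the threshold and on single arrays: rises outnumbered falls at a 2-fold minimum, at an adjusted p of 0.01 (1298 and 1255), without vehicle replicate 1 (1267 and 1196) and without vehicle replicate 2 (1335 and 1237). The total was 2463 and 2572 calls in the last 2 fits, against 5023 with all arrays. A plain test without pooled variance called 1 gene, INA, a neuronal intermediate filament gene named here after its values were seen (log2 fold change 5.90).

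Cancer/testis antigens rose more often than other genes. Of 157 antigens tested, 68 rose and 13 fell, and adjusted over the list alone 71 rose and 15 fell. The share of rises was 43.3% among antigens and 12.1% among the 17801 other genes (odds ratio 5.53, 95% interval 3.96 to 7.69, two-sided Fisher exact adjusted p = 1.39e-21), and the odds ratio ran from 4.64 to 8.27 with 1 array left out. Rises reached at least 2-fold for 55 antigens and at least 16-fold for 17. Of the 59 antigens on the X chromosome with a probe set of their own, 36 rose and 1 fell (37 and 1 adjusted over the list alone), with a median log2 fold change of 1.63. Besides MAGEA4 and TKTL1, they included SSX3, a transcriptional repressor gene (36.4-fold, SE 0.13 on the log2 scale), and TFDP3, a germ cell member of the DP family (34.9-fold, SE 0.12). The X-linked list passed camera (adjusted p = 6.00e-19, and adjusted p = 0.173 with an estimated correlation). The fall was of CSAG3 (log2 fold change -0.49, adjusted p = 0.0473, named after its value was seen), and it was not called without vehicle replicate 1, vehicle replicate 2 or treated replicate 2, nor under either other scaling.

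Of 98 autosomal antigens, 32 rose and 12 fell (34 and 14 adjusted over the list alone), with a median log2 fold change of 0.01 and a mean of 0.59. The rises were led by MAEL, a piRNA-pathway protein (52.5-fold), BRDT, the testis bromodomain protein (41.7-fold), ELOVL4, a fatty acid elongase (37.4-fold), and PIWIL2, a germline Argonaute protein (31.5-fold), with SE between 0.11 and 0.17. This list also passed camera (adjusted p = 0.00206, and adjusted p = 0.315 with an estimated correlation), as higher. Without vehicle replicate 2 the counts were 21 rises and 4 falls, and without vehicle replicate 1 there were 6 falls; with housekeeping centring there were 7 falls, and without the dimmest 33.3% of genes 20 rises. Coverage of the lists differed: 59 of 128 X-linked and 98 of 117 autosomal symbols were tested, the others having no probe set that names them alone. Among tested members, the share of rises was larger in the X-linked list (61.0%) than in the autosomal list (32.7%; odds ratio 3.23, 95% interval 1.56 to 6.69, Fisher exact adjusted p = 0.00108). With 1 array left out this odds ratio ran from 2.95 to 5.74. The 12 autosomal falls included genes bright in vehicle, such as PBK, KIF2C and TTK (levels 9.52 to 10.47, named after their values were seen). The content of the lists was therefore not separated from the chromosome.

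**Figure D2:**
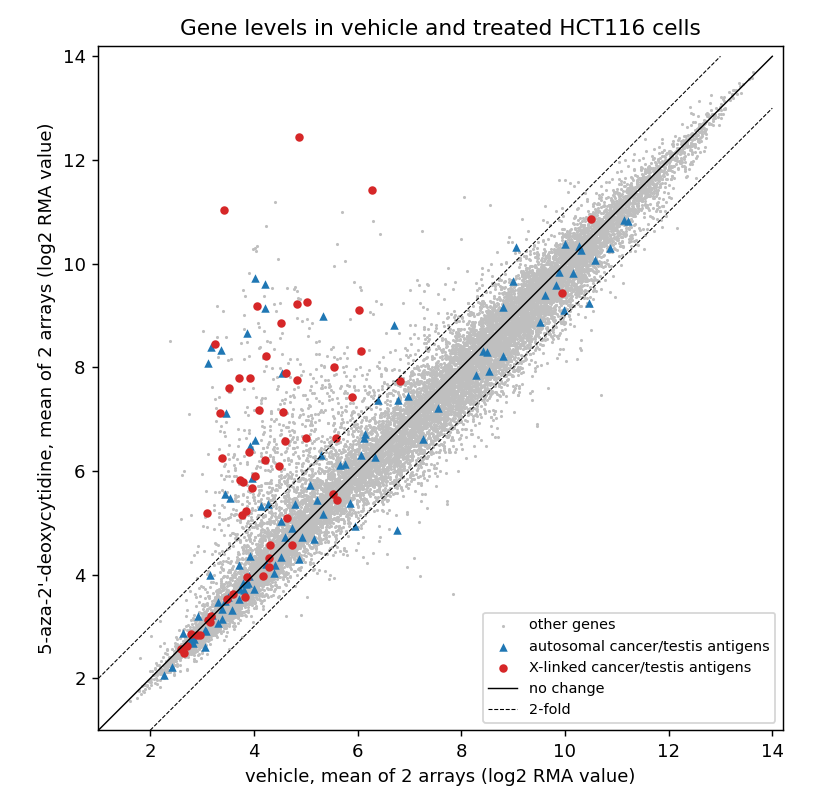
Mean log2 RMA value of 2 treated arrays against that of 2 vehicle arrays for 17958 genes (grey), with the 59 X-linked (circles) and 98 autosomal (triangles) cancer/testis antigens marked; the solid line is no change and the dashed lines are 2-fold changes. Of the antigens, 36 X-linked and 32 autosomal ones rose, most of them from low vehicle levels.

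Genes of germ cells and meiosis rose as a group. Of 62 tested, 37 rose and 5 fell (42 and 7 adjusted over the list alone), with a median log2 fold change of 0.83 (camera adjusted p = 9.77e-17, and adjusted p = 0.173 with an estimated correlation). Besides DAZL and MAEL, TEX11, a meiotic protein encoded on the X chromosome, rose 51.0-fold (SE 0.14, log2), and DPPA3, a maternal-effect gene of germ cells, rose 26.3-fold (SE 0.11). The list shares 12 genes with the autosomal antigens. The falls, named after their values were seen, were of MOV10, TDRKH, SYCE2, SPO11 and PIWIL1, with log2 fold changes between -0.64 and -0.45. Without vehicle replicate 1, vehicle replicate 2 and treated replicate 1 the falls numbered 0, 1 and 2, with housekeeping centring 1, and without the dimmest 33.3% of genes 14 rises and 3 falls were called.

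Genes often hypermethylated in colorectal cancer and imprinted genes also rose as groups. Of 65 genes of the hypermethylated list, 30 rose and 3 fell (31 and 5 adjusted over the list alone; camera adjusted p = 1.78e-07, and adjusted p = 0.173 with an estimated correlation). UCHL1 was followed by VIM, the mesenchymal filament vimentin (39.0-fold, from 5.71 ± 0.42 to 10.99 ± 0.07), SPARC, a matricellular protein (22.8-fold), and FBN2, a fibrillin (11.3-fold). Of 33 imprinted genes, 14 rose and 3 fell (14 and 4 adjusted over the list alone; camera adjusted p = 0.000258, and adjusted p = 0.315 with an estimated correlation). After NNAT came FAM50B (6.64-fold), the noncoding RNA MEG3 (6.27-fold) and DLK1, a Notch-ligand relative (4.18-fold). MEG3 and DLK1 belong to the same imprinted domain. Without vehicle replicate 1 and without vehicle replicate 2 the rises numbered 19 and 20 in the hypermethylated list (1 and 0 falls) and 9 in both fits in the imprinted list (0 falls), while centring left 0 imprinted falls and repeated quantile normalization gave 5. Without the dimmest 33.3% of genes 5 genes of the hypermethylated list fell. The falls, named after their values were seen, were of MGMT, RASSF2 and FBLN1 in the first list and of TP73, L3MBTL1 and MKRN3 in the second, with log2 fold changes between -0.87 and -0.39. In the same samples 12 of 38 markers of fibroblasts, endothelium and leukocytes rose.

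Transcripts of the DNA methyltransferases did not pass the test. DNMT1, the maintenance enzyme, had a log2 fold change of -0.12 (SE 0.12, adjusted p = 0.540), DNMT3A of 0.10 (SE 0.12, adjusted p = 0.571) and DNMT3B of 0.09 (SE 0.11, adjusted p = 0.617). Of the 21 genes of the DNA methylation and deoxycytidine metabolism list, 3 rose and 4 fell (4 and 4 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.713). MBD1, a methyl-CpG binding protein, rose 1.68-fold. DCTD, a deoxycytidylate deaminase, fell 1.75-fold, and DCK, the kinase that phosphorylates deoxycytidine and its analogs, fell by 0.68 on the log2 scale. UHRF1, the partner of DNMT1 at replicated DNA, fell 1.49-fold. SE on the log2 scale lay between 0.12 and 0.13 for these 4 genes. The remaining calls, named after their values were seen, were rises of TET2 and ZBTB38 and a fall of TET1 (log2 fold changes 0.58, 0.49 and -0.62). The list had 1 rise without vehicle replicate 1, and 2 rises and 1 fall without vehicle replicate 2.

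Cell cycle genes fell. Of 56 tested, 35 fell and 0 rose in limma's test, with 0 higher and 41 lower at an unadjusted p under 0.05 (37 falls adjusted over the list alone; camera adjusted p = 1.25e-09, and adjusted p = 0.295 with an estimated correlation), with a median log2 fold change of -0.57 that stayed at -0.45 after housekeeping centring. E2F8 and E2F2, transcription factors of the cell cycle, fell 2.77-fold and 2.34-fold, the nuclear lamina gene LMNB1 fell 2.23-fold, and MCM10, a replication initiation factor, fell 1.85-fold (SE between 0.12 and 0.13, log2). The falls numbered 14 without vehicle replicate 1 and 19 without vehicle replicate 2. Targets of p53, which is wild type in this line, moved the other way: of 43, 17 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 6.61e-05, and adjusted p = 0.295 with an estimated correlation). EDA2R, a TNF receptor family member, rose from 4.44 ± 0.26 to 6.44 ± 0.31, SPATA18 rose 2.33-fold and the kinase PLK2 2.18-fold, while KITLG fell 2.24-fold. The rises numbered 7 without vehicle replicate 1 and 8 without vehicle replicate 2, and repeated quantile normalization gave 2 falls.

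Replication-dependent histone genes went both ways: of 48, 16 rose and 19 fell (18 and 20 adjusted over the list alone), with a median of -0.22, a mean of 0.35 and no call as a group (camera adjusted p = 0.562). H3C11 (27.3-fold), H1-5 (25.2-fold), H1-1 (13.1-fold) and H2AC8 (10.3-fold) rose, from vehicle levels of 2.64 to 5.61. Members of this family are near-identical. In the integrated stress and unfolded protein response list 8 of 30 genes rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0830). ATF3, a stress-induced transcription factor, rose 2.80-fold, CHAC1, a glutathione-degrading enzyme, rose 2.66-fold and VLDLR rose 2.23-fold, while PHGDH, the first enzyme of serine synthesis, fell 2.13-fold; the other falls, named after their values were seen, were of SLC7A11 and DDIT4 (log2 fold changes -0.93 and -0.60). The list passed without treated replicate 2 (adjusted p = 0.0317) and after repeated quantile normalization (adjusted p = 0.0266), and over all settings its adjusted p ran from 0.0266 to 0.480. Without treated replicate 1 it had 5 falls.

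Interferon-stimulated genes went both ways. Of 58 tested, 17 rose and 7 fell (19 and 8 adjusted over the list alone), with a median log2 fold change of -0.01, which became 0.10 with housekeeping centring, and a mean of 0.19 (camera adjusted p = 0.0740, higher). MX2, an antiviral GTPase, rose 6.56-fold (from 4.16 ± 0.25 to 6.87 ± 0.15), IFI27 rose 5.86-fold and IRF7, an interferon regulatory factor, 2.68-fold. USP18, a negative regulator of interferon signaling, fell 2.58-fold (SE 0.14, log2). Leaving out vehicle replicate 1 gave 9 rises and 4 falls. Without treated replicate 2 the list passed camera (adjusted p = 0.0308, in a range of 0.0308 to 0.391 over all settings). Of 26 antigen processing and presentation genes, 4 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.470). The list passed limma's fry as lower (adjusted p = 0.0319), a test of whether its genes move 1 way on balance, without comparison to other genes. CD74, the MHC class II invariant chain, rose 4.02-fold, whereas the class II gene HLA-DRA fell 2.77-fold, PSMB9, an immunoproteasome subunit, fell 2.62-fold and NLRC5, a class I transactivator, fell by 0.85 on the log2 scale. The other rises, named after their values were seen, were of HLA-DPA1, HLA-DPB1 and PSMB8 (log2 fold changes 0.66, 0.48 and 0.46). Without vehicle replicate 1 and without vehicle replicate 2 both fits gave 1 rise and 3 falls, and housekeeping centring gave 4 and 3.

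Of 32 intestinal differentiation genes, 8 rose and 1 fell, also adjusted over the list alone, with a median log2 fold change of -0.01 and a mean of 0.30 (camera adjusted p = 0.0763, higher). The brush border peptidase ANPEP rose 17.5-fold, KRT20, a keratin of mature colonocytes, 5.10-fold and LGALS4, a galectin, 3.40-fold, and ATOH1, the secretory lineage factor, fell 2.25-fold. The list passed without vehicle replicate 2 (adjusted p = 0.0395), without treated replicate 1 (adjusted p = 0.0300) and without the dimmest 33.3% of genes (adjusted p = 9.10e-05), and its adjusted p reached 0.616 with an estimated correlation. There were 5 rises without vehicle replicate 1, 3 falls without treated replicate 2, 2 falls after repeated quantile normalization and 0 falls without the dimmest 33.3% of genes. Of 21 WNT target genes, 9 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.00623, and adjusted p = 0.480 with an estimated correlation). LEF1, a transcription factor of the pathway, rose 5.99-fold, AXIN2 2.14-fold, NKD1 1.98-fold and NOTUM 1.82-fold. The last 3 of these are feedback inhibitors of the pathway. Without vehicle replicate 1 and without vehicle replicate 2, 4 genes rose in both fits, with 0 and 1 falls, and housekeeping centring and the filter on dim genes gave 1 fall each. The falls were of TNFRSF19 and CD44 (log2 fold changes -0.73 and -0.50, named after their values were seen).

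Markers of fibroblasts, endothelium and leukocytes, cell types other than the carcinoma line, included 12 rises and 1 fall among 38 genes (14 and 1 adjusted over the list alone; camera adjusted p = 6.61e-05, and adjusted p = 0.315 with an estimated correlation). The cell surface protein THY1 rose 8.89-fold, the collagen COL6A3 6.22-fold, endoglin (ENG) 5.76-fold and CD3D, a T cell receptor subunit, 3.47-fold. Treated levels of these 4 genes lay between 6.62 and 7.72. The fall was of KDR (log2 fold change -0.55, named after its value was seen), and it was not called without vehicle replicate 1 or vehicle replicate 2 or with housekeeping centring, while 2 falls were called without treated replicate 1 and after repeated quantile normalization and 0 without the dimmest 33.3% of genes. Metallothionein genes had 0 calls in limma's test among 10 genes, also adjusted over the list alone, and 1 higher and 0 lower at an unadjusted p under 0.05, with adjusted p of 0.0654 for MT1G (log2 fold change 0.42, SE 0.14) as the smallest. This absence of calls depended on the processing, since 1 rise was called under both other scalings, with the other variance prior and without the dimmest 33.3% of genes. MT1M, MT3 and MT4 had log2 fold changes of 0.23, 0.17 and 0.26. Of 23 housekeeping genes POLR2A rose 1.53-fold and GPI fell 1.38-fold over all genes tested, and none passed adjusted over the list alone; without vehicle replicate 1 and without vehicle replicate 2 there were 0 calls. Housekeeping falls numbered 4 without treated replicate 1 and with the other variance prior, 3 without the dimmest 33.3% of genes, 2 with the mean of probe sets and 0 with housekeeping centring. Centring sets the mean of this list equal on all arrays, so its 0 falls under that setting are largely built in. SDHA and VPS29 had log2 fold changes of -0.38 and -0.46. Neither list passed camera (adjusted p = 0.228 and 0.501), except that the metallothionein list passed without treated replicate 1 (adjusted p = 0.0465, in a range of 0.0465 to 0.792 over all camera settings), with 1 rise.

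**Figure D3:**
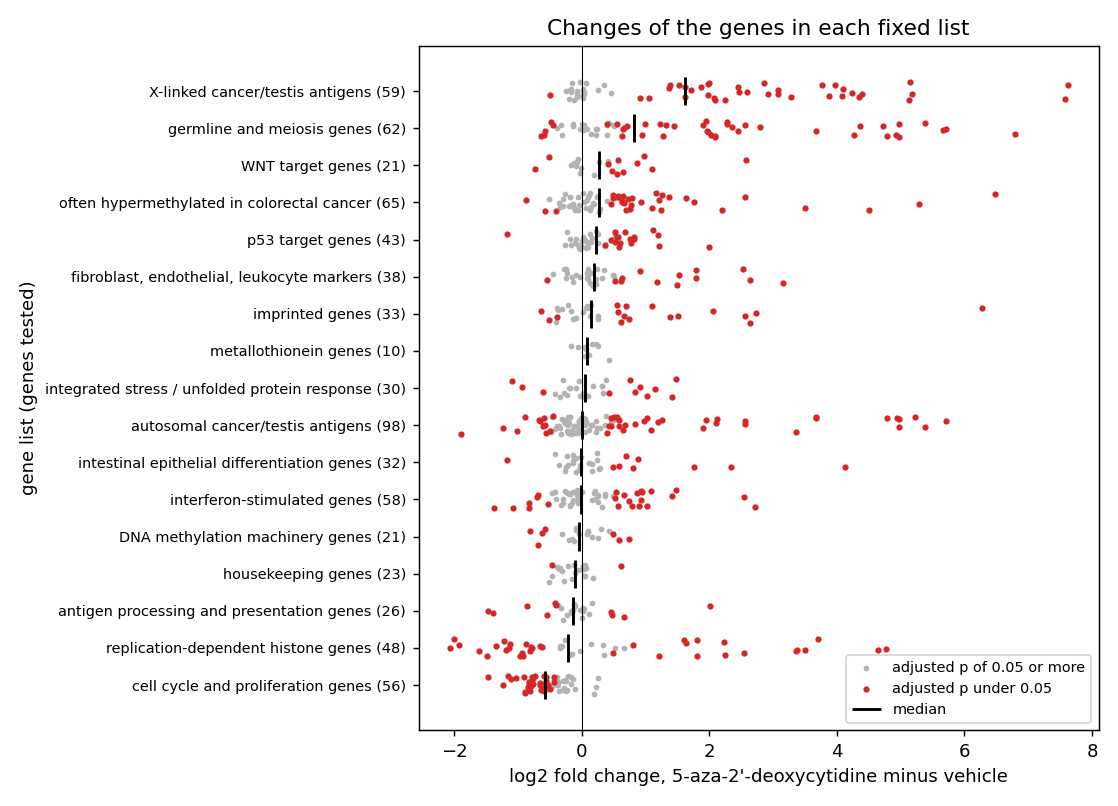
Log2 fold change (treated minus vehicle) of each gene of the 17 lists, with the number of genes tested in parentheses; red points have an adjusted p under 0.05, grey points do not, and the black bar is the list's median. Medians run from -0.57 for cell cycle genes to 1.63 for X-linked cancer/testis antigens.

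The X chromosome held a larger share of rises than the other chromosomes, 127 of 689 genes (18.4%) against 2099 of 17241 (12.2%; odds ratio 1.63, 95% interval 1.33 to 1.99, Fisher exact adjusted p = 7.72e-06; 1.47 to 2.26 with 1 array left out). Without the X-linked antigens of the fixed list, 91 of 630 genes on X rose (14.4%; odds ratio 1.22, 95% interval 0.960 to 1.53, Fisher exact adjusted p = 0.0946). This second test passed with 1 of the vehicle arrays left out (odds ratio 1.45 without vehicle replicate 1 and 1.52 without vehicle replicate 2).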

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

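Probe sets outside the comparison of named genes held signal above the vehicle arrays; the decision to count them was made after the named genes had been tested. Of 2055 probe sets that list several genes, 349 were higher in treated cells and 226 were lower. Among them, 43 list several cancer/testis antigens of the fixed lists and no other gene, and 39 of these were higher and 2 lower. Some carry identical values: the 43 hold 27 distinct sets of values, of which 24 were higher and 2 lower. The largest rise was 8.70 on the log2 scale, on a probe set listed for 3 genes of the GAGE family. Of the 12061 probe sets without a listed gene, 37 were higher and 6 lower. The adjusted p-values come from limma over the 2055 probe sets, the 43 included, and over the 12061 apart from them, and which single genes the probe sets measure was not resolved.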

How the results depend on the processing

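Among the 85 named genes, 99 values under the alternatives lost the call and 16 gained one, but no setting reversed a called direction, and no list changed its called direction. The 99 include every named call under the plain test, which called only INA, a gene outside the 85. They also include calls removed by the 2-fold minimum or the adjusted p of 0.01 by definition, such as that of GPI. The 99 are therefore not a measure of dependence on processing alone. The count of 5023 genes was 2553 at an adjusted p of 0.01 (1298 higher, 1255 lower), 1377 at a 2-fold minimum (907 higher, 470 lower), and 1 by the plain test (1 higher, 0 lower, with 4723 genes at an unadjusted p under 0.05), which has 2 degrees of freedom per gene; with so few calls its shares of rises were not compared. Centring on housekeeping genes left 1843 falls. Leaving out 1 array gave 2463 to 5931 changed genes, 1267 to 2530 higher and 1196 to 3401 lower, and 9 to 11 called lists; with 1 array in a group, that array is assumed to vary like the other group's. For the results cancer/testis antigen genes changed and cancer/testis antigen genes higher, the counts were 128 and 114 when every probe set with a symbol was counted, 124 and 109 when probe sets naming several antigens were added, and 0 and 0 by the plain test; without the dimmest 33.3% of genes, 44 were higher, fewer antigens being tested by construction. Leaving out 1 array gave 61 to 83 changed antigens (57 to 70 higher). Of the 17 lists 9 passed camera, 0 did with an estimated correlation, and 10 passed fry, these 9 and antigen processing and presentation as lower. The odds ratio for chromosome X without listed antigens passed its test at an adjusted p of 0.01 (1.38) and 0.1 (1.23), at a 2-fold minimum (1.41), and with either vehicle array left out (range over left-out arrays 1.1 to 1.52); the cause was not tested. Whether equal replicate numbers pair samples is not known: the labels do not say so, the differences between arrays 1 and 2 correlated at 0.27 between the groups, and the fit with the replicate number as a block called 6639 genes, including all 5023, with 9 lists called. With that block MT1G, SDHA and VPS29 gained a call, and no call on the 17 lists or the 4 shares compared in the report changed; the families, chromosomes and neighbours were not tested with it. What limits all results is the 2 arrays per group and the absence of detection calls for dim genes.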

Other observations

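The tests of gene families, chromosomes, neighbours and vehicle level reported here were not among the planned comparisons. The camera test of the interferon list was planned, but the bounds for a coordinated response of that list were set after its counts were seen. Genes were grouped by the letters at the start of their symbols, which gave 322 families of 8 or more genes and 644 tests, of which 8 passed. Zinc finger genes of the ZNF series rose more often than other genes, 119 of 486 (53 fell; Fisher exact adjusted p = 4.48e-11), with 142 rises after housekeeping centring and 125 after repeated quantile normalization. The 4 with the smallest p-values, named after their values were seen, were ZNF140, ZNF506, ZNF560 and ZNF549, with log2 fold changes of 3.22, 2.99, 4.18 and 2.99 (SE 0.12 to 0.18). Chromosome 19 held 226 rises among 1255 genes (odds ratio 1.61, adjusted p = 9.29e-08). Besides X, chromosome 11 also passed this test, with fewer rises than elsewhere (113 of 1205, odds ratio 0.714, adjusted p = 0.00526). On chromosome 19, 33.6% of ZNF genes rose against 14.5% of the others (odds ratio 2.99, 95% interval 2.13 to 4.18); off it the shares were 16.1% and 11.9% (odds ratio 1.42, 95% interval 0.986 to 2.00). Olfactory receptor genes gave few calls: 5 of 356 rose and 15 fell (Fisher exact adjusted p = 8.88e-12 for rises and 2.79e-09 for falls, both fewer than elsewhere), and 7 rose and 5 fell after housekeeping centring. This test compared the family with all other genes and was not matched on vehicle level. In the lowest of 3 bins of 5986 genes by vehicle mean, 1013 rose and 215 fell. Few falls were thus also seen among dim genes in general, but rises were not few there. Whether the few rises of olfactory receptor genes and those of chromosome 11 are separate results was not tested. Of the 8 lists called higher, the number of rises was reached by 0 of 10000 random lists matched on vehicle level, except for the fibroblast, endothelial and leukocyte markers (296 of 10000). Genes were drawn singly for the random lists, here and below. These counts thus do not allow for list members that move together or share probes, and they are not p-values for the lists.

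Outside the fixed lists, 1 family passed with most of its members called in 1 direction: genes of intraflagellar transport (IFT), which builds cilia, of which 10 of 17 fell (adjusted p = 0.00593, median log2 fold change -0.60; 7 falls with housekeeping centring and 7 with repeated quantile normalization). With 7 falls most members were no longer called, and the family test was not repeated under either of these scalings. IFT140 fell by 1.45 and IFT52 by 0.89 on the log2 scale. The other families that passed were TMEM (56 of 207 fell, adjusted p = 0.00297), MCM, which overlaps the cell cycle list (8 of 11 fell, adjusted p = 0.00464), CEP (15 of 36 fell, adjusted p = 0.0143) and ZFP (9 of 20 rose, adjusted p = 0.0257). The family tests were not matched on vehicle level. Of the 5986 genes in each bin by vehicle mean, 215 fell in the dim, 1318 in the middle and 1261 in the bright bin. Whether the falls of IFT, TMEM, MCM and CEP genes exceed those of genes of like level was not tested. Histone genes brighter than the median gene in vehicle (7.14) had 3 rises and 17 falls among 28. The dimmer ones had 13 rises and 2 falls among 20 (two-sided Fisher exact p = 0.000133 for rises). Under both other scalings there were 4 rises and 16 or 17 falls among the brighter and 14 or 12 rises among the dimmer genes. The direction of this split was not particular to histones. In 3 bins of 5986 genes by vehicle mean, 1013 rose and 215 fell in the dim bin. In the bright bin 393 rose and 1261 fell. The Fisher test compared histones only with each other. In random lists matched on vehicle level 2 to 10 genes rose (central 95%), against 16 histone genes. Neighbouring genes with different symbol starts both rose in 279 pairs, against 222 to 278 in the central 95% of 10000 shuffles within chromosomes and 303 at most, so whether rises cluster along chromosomes is left open.

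The rises of at least 2-fold were concentrated among genes dim in vehicle: of 5986 genes in each of 3 bins by vehicle mean, 613 in the dim, 263 in the middle and 31 in the bright bin rose that much. Falls of at least 2-fold numbered 8, 258 and 204 in the same bins. Because the bins were made on vehicle level, genes at the low end of the scale had little room to fall and the brightest little room to rise. How far this shaped the pattern was not tested. The tables argue against 2 technical causes. Ranked by vehicle replicate 1 alone, 9 genes of the lowest bin were 2-fold higher in vehicle replicate 2 and 634 in the treated mean. Regression to the mean from noise between the 2 vehicle samples thus gives 1.42% of them. If these samples are technical, the check does not cover variation between cultures. The median dim gene changed by -0.040 on the log2 scale, against a lift of dim probe sets as a whole by normalization. Reactivation of silenced genes by the treatment may explain the pattern and stays open as a hypothesis, since methylation was not measured.

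Part of the interferon list rose (17 of 58). In random lists matched on vehicle level 3 to 13 genes rose (central 95%), so 17 rises lie above the range for genes of like level drawn singly. The draws do not allow for members that move together, so this range may be too narrow to exclude low vehicle level alone. Of the members 29.3% were higher and 12.1% lower, but bounds for a coordinated response were set after these counts were known and decide nothing. An interferon response may explain the rises and stays open, as do rises of single genes.

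Part of the list of fibroblast, endothelial and leukocyte markers rose (12 of 38). Cells of these types would bring their abundant transcripts, listed before the test, but the highest median log2 change of such transcripts over the 3 cell types was 0.25: COL1A2 changed by 0.11, DCN by 0.25, LUM by 0.14, VWF by 0.33, CDH5 by 0.18, PTPRC by 0.10 and LYZ by -0.27, none past the test. Other such transcripts did pass: the fibroblast markers COL1A1 and SPARC rose by 0.63 and 4.51, the endothelial markers ENG and PECAM1 by 2.53 and 1.79, and the leukocyte markers CD3E, CD68 and CD74 by 0.92, 1.53 and 2.01, while the endothelial marker KDR fell by 0.55. Random lists matched on vehicle level had 3 to 12 rises, so the 12 rises lie at the upper edge of that range, but the list's mean log2 change of 0.522 lay above that of 98.93% of these lists. Whether low vehicle level alone accounts for the rises is left open.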
